A study of Drosophila melanogaster with 4 samples.

How the data were processed

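Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on wild-type Oregon-R embryos of Drosophila melanogaster aged 14 to 16 h with an antibody, coded Q4443, against dMi-2. Formaldehyde-crosslinked chromatin was immunoprecipitated and compared with input DNA, per the labels' protocols. The labels give 4 libraries, namely 2 ChIP libraries and 2 input libraries, each numbered replicate 1 and 2. Each input is named as the control of 1 ChIP replicate. The labels do not say whether the replicates came from separate embryo collections, so differences between them may be technical in part.

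The deposited data used here are 3 lists of enriched regions in GFF3 format: 1 list for each ChIP replicate and 1 combined list for the series. Bowtie 0.12.7 is named in the submitters' processing notes. The genome build is FlyBase release 5, per the file headers. The region caller, its version, its settings and the read filters are not given in the sources used here, and the same sources do not state whether the combined list came from pooled reads. Per the file headers and columns, each region has a chromosome, a start, an end and a deposited score, whose scale the authors' files do not name. The scores are the authors' own and were used to describe, rank or filter regions within a list, and their levels were not compared between lists. The only use across lists is the correlation of scores over overlapping regions. The smallest region is 1301 bp in both replicate lists and 1001 bp in the combined list. All starts in the combined list are even numbers, against 49.4% and 50.3% in the replicate lists. No read counts accompany the lists, so the depth behind a region is unknown and intervals given for shares of regions cover counting error only. One region end written in exponent form was read as its full number.

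The tests, the alternatives, the groups of genes to test and the rule for naming regions were fixed before the data were examined. Regions of 2 lists were called shared when they overlapped by at least 1 bp, with counts checked against bedtools 2.31.1. Chance overlap was estimated from 1000 circular shifts of the other list within each sequence, giving a one-sided permutation p of at least 0.001. Scores and widths of shared and unshared regions were compared by the difference of medians. Scores were tested with 100000 permutations of the shared status, two-sided, giving a p of at least 1e-05. As overlap by itself favours wide regions, widths were set against circular shifts of the other list, and scores were also compared within deciles of width (10000 permutations within deciles), both added after the data had been seen. Score agreement was computed across overlapping pairs of regions as Pearson's r of log-transformed scores, as planned, and of scores as deposited, and Spearman's rho, with 100000 permutations. Density per chromosome arm was compared over the 6 major arms (2L, 2R, 3L, 3R, 4 and X) with a two-sided exact binomial test against the share of length, using lengths in the file headers and Benjamini-Hochberg adjustment over the 6 arms. Spacing was compared with 1000 random placements of the same regions, without overlap, on the same sequences. These tests treat regions as units and do not measure variation between embryo collections. Intervals of shares of regions are 95% exact binomial intervals (Clopper-Pearson), and those of score differences and densities on X are 95% bootstrap intervals over 500-kb blocks (1000 draws, and 300 for the stratified differences). Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used.

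The overlap test was tested on simulated data of 4209 regions. Planted shares of 30% and 60% were recovered as 30.9% and 60.4% after correction for the chance overlap of the unplanted regions, which is known only in a simulation. The shares in the Results are raw and have no such correction. Without sharing, 3.3% of 60 simulations passed the 0.05 threshold. Simulated regions were placed at random, so this rate need not hold for clustered lists. For spacing, 0.0% of 40 simulations of randomly placed regions passed it.

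The named regions are the 10 highest-scoring regions of the combined list that overlap both replicates, the 5 widest regions of the combined list, the 5 windows of 50 kb with most covered sequence, and the 3 highest-scoring regions of each replicate with no overlap in the other. The planned assignment of regions to genes, promoters and groups of genes was not carried out. The gene table used here is on Release 6 of the genome, its coordinates cannot be set beside release 5 coordinates, and none were converted. Regions are therefore given by position only. Alternatives tried were a reciprocal overlap of 50%, centres within 250 bp, the regions of each list at or above its median score, the major arms only, merging of regions closer than 1000 bp, covered length in place of number, each replicate's own list in place of the combined one, and pairing rules and scales for the score agreement. A permutation of 100-kb windows between arms, arm ratios with X left out of the comparison, a width minimum on the combined list, the major arms for the score agreement, and merging for the spacing were added after the data had been seen.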

Results

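The genomic distribution of dMi-2 was profiled by ChIP-seq in wild-type embryos aged 14 to 16 h. dMi-2 is an ATP-dependent nucleosome remodeller of the CHD family and a subunit of the NuRD and dMec complexes of Drosophila. The design sets 2 ChIP replicates against their own inputs, and it addresses where in the late embryonic genome dMi-2 is enriched. The replicate 1 list held 4213 enriched regions covering 9.70 Mb, and the replicate 2 list held 5359 regions covering 13.98 Mb. The combined list held 9388 regions covering 25.32 Mb. On the 6 major arms, which total 120.4 Mb, these lists covered 8.06%, 11.6% and 21.0% of the sequence, respectively. The median width was 1969 bp in replicate 1, 2101 bp in replicate 2 and 2043 bp in the combined list. Regions of 10 kb or more numbered 7, 28 and 100. No region had identical coordinates in both replicates.

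Most dMi-2 regions of replicate 1 were found again in replicate 2, and nearly all regions in the highest-scoring decile of either list were shared, though not the single highest-scoring region of each list. Of the replicate 1 regions, 3369 of 4213 (80.0%, interval 78.7 to 81.2) overlapped a replicate 2 region. Of the replicate 2 regions, 3243 of 5359 (60.5%, interval 59.2 to 61.8) overlapped a replicate 1 region. Circular shifts gave a mean of 20.6% and at most 27.7% for replicate 1, and a mean of 16.2% and at most 21.6% for replicate 2 (permutation p = 0.001 in both, one-sided, the smallest that the shifts can give). The sequence covered in both replicates was 7.42 Mb, which is 76.5% of the replicate 1 coverage and 53.1% of the replicate 2 coverage. The share depended on the definition of overlap. With centres within 250 bp it was 32.5% for replicate 1 and 25.5% for replicate 2, against shifted means of 2.25% and 1.77%.

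The shared share rose with the authors' score. In the highest-scoring decile, 402 of 422 replicate 1 regions (95.3%, interval 92.8 to 97.1) and 511 of 536 replicate 2 regions (95.3%, interval 93.2 to 97.0) were shared. In the lowest-scoring decile the shares were 72.5% (interval 68.0 to 76.7) and 40.9% (interval 36.7 to 45.2). Shared regions of replicate 1 had a median score of 0.633, against 0.594 for the 844 unshared regions, a difference of 0.04. In replicate 2 the medians were 0.663 for shared and 0.577 for the 2116 unshared regions, a difference of 0.09. An overlap of 1 bp is met more often by wider regions, and shared regions were wider, with medians of 2081 bp against 1534 bp in replicate 1 and 2599 bp against 1726 bp in replicate 2. These width differences of 547 bp and 873 bp compare with means of 106 bp and 226 bp, and at most 253 bp and 535 bp, when the other list was shifted (permutation p = 0.001 in both, one-sided, the smallest that the shifts can give). The score differences had a permutation p of 1e-05, two-sided, the smallest that 100000 permutations can give, and they exceeded those with the other list shifted, at most 0.0318 in replicate 1 and 0.0453 in replicate 2 (permutation p = 0.001 in both, one-sided). At equal width they turned negative in replicate 1 and were much smaller in replicate 2. Within deciles of width that held at least 20 regions of each kind, a setting chosen after the data had been seen, the difference in score was -0.0196 in replicate 1 and 0.00865 in replicate 2 (permutation p = 1e-04, the smallest possible, and 0.017, two-sided). These values rest on 7 deciles with 2949 regions in replicate 1 and on 9 deciles with 4823 regions in replicate 2. With the thinly filled deciles kept, the difference was -0.0051 and 0.0185. With sharing defined by centres within 250 bp, the differences over all widths were 0.01 and 0.04 in score and 172 bp and 283.5 bp in width. Across 3521 overlapping pairs of regions, the scores of the replicates correlated with a Spearman rho of 0.505 and a Pearson r of 0.617 on scores as deposited (permutation p = 1e-05 for both). The planned Pearson r on log-transformed scores was 0.556, which is a log of values that already have the form of log2 ratios. This correlation is across regions, which are not independent replicates.

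**Figure D1:**
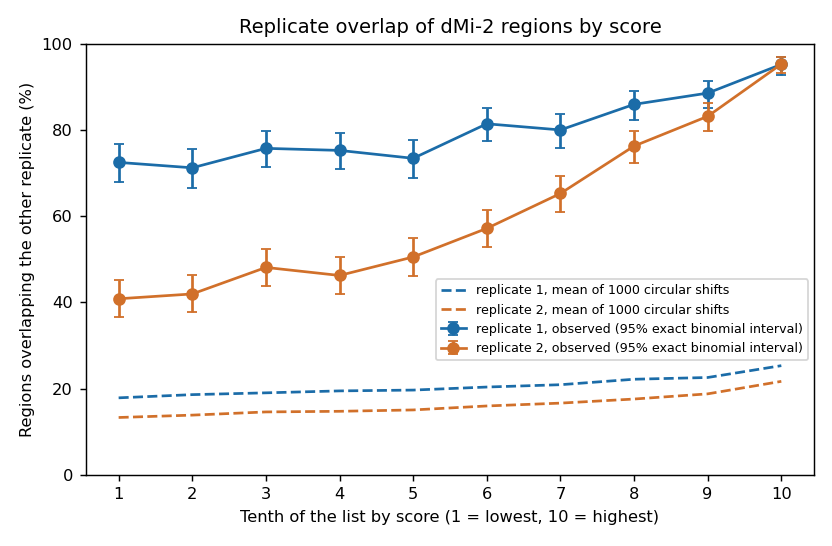
Percentage of regions of each replicate that overlapped a region of the other replicate, by decile of the list ranked on the authors' score, with 95% exact binomial intervals as error bars and the mean of 1000 circular shifts as dashed lines. Both replicates reached 95.3% in the highest decile, while the lowest decile stood at 72.5% in replicate 1 and 40.9% in replicate 2.

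The strongest dMi-2 regions present in both replicates lay on 2L, 2R, 3R, X and the unplaced scaffold U. The highest-scoring one of the combined list was on U at 9169264 to 9172032 (2.8 kb, score 2.06), which ranked 2 in the lists of both replicates. Of the 19 combined-list regions on U, only this 1 overlapped both replicates, and how well reads could be placed on U is unknown. On the major arms the highest was on X at 5417228 to 5419646 (2.4 kb, score 1.78), ranked 3 in replicate 1 and 4 in replicate 2. It was followed by 2R at 15611782 to 15617844 (6.1 kb, score 1.47, ranks 5 and 6) and 3R at 2637300 to 2649794 (12.5 kb, score 1.37, ranks 4 and 3). A further 3 were on 2R, at 19726360 to 19728844 (ranks 10 and 12), 20962408 to 20965666 (ranks 16 and 10) and 9314680 to 9321270 (ranks 8 and 5). The remaining 3 were on 2L, at 477850 to 487166 (ranks 19 and 7), 11997172 to 12014478 (ranks 13 and 8) and 14597380 to 14600814 (ranks 12 and 24). These 10 regions ranked between 2 and 19 in replicate 1 and between 2 and 24 in replicate 2 by their highest-scoring overlapping region. In the combined list itself they ranked from 38 to 63, and the 37 regions with higher scores overlapped neither replicate list.

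The highest-scoring regions found in 1 replicate alone lay mostly on X and on sequences outside the major arms. In replicate 1 they were on the scaffold 3RHet at 2463393 to 2464758 (score 2.67, the highest of its list), on X at 16793304 to 16794818 (score 0.912, rank 141) and on 2L at 7731407 to 7732951 (score 0.905, rank 151). In replicate 2 they were on U at 9643528 to 9644975 (score 2.80, the highest of its list), on X at 13070827 to 13072182 (score 1.03, rank 72) and on X at 1421186 to 1422910 (score 0.942, rank 167). The 3RHet region, the U region and the first X region of replicate 1 had no overlap in the combined list.

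The combined list took in nearly all replicate regions and added many narrower ones. It overlapped 4184 of the 4213 replicate 1 regions (99.3%) and 5320 of the 5359 replicate 2 regions (99.3%). Of its 9388 regions, 2985 (31.8%, interval 30.9 to 32.7) overlapped both replicates, 724 (7.71%) only replicate 1, 1864 (19.9%) only replicate 2, and 3815 (40.6%, interval 39.6 to 41.6) neither. Regions in both replicates had a median width of 3799 bp and made up 13.48 Mb of the combined coverage. Regions in neither had a median width of 1337 bp and made up 5.64 Mb. Median scores within the combined list were 0.551 for regions in both replicates and 0.410 for regions in neither. The share in both replicates was 20.2% with a reciprocal overlap of 50% and 10.1% with centres within 250 bp. The share in neither was 61.0% with centres within 250 bp and 27.0% without regions narrower than 1301 bp, a setting chosen after the data had been seen.

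Regions were densest on 2R, sparser on 2L and sparsest on chromosome 4, the small, largely heterochromatic chromosome of Drosophila. In the combined list, 2R carried 86.9 regions per Mb, 1.15 times the density of the other major arms together (exact binomial test, adjusted p = 4.6e-07). Arm 2L carried 71.2 per Mb, a ratio of 0.900 (exact binomial test, adjusted p = 0.00021). Chromosome 4 carried 39 regions, or 28.8 per Mb, a ratio of 0.369 (exact binomial test, adjusted p = 1.4e-12). The binomial test takes regions as independent, although they cluster. A permutation of 100-kb windows between arms, chosen after the data had been seen, gave adjusted p = 0.0048 for 2R, 0.047 for 2L and 6e-04 for chromosome 4. Arms 3L, 3R and X had 77.4, 78.1 and 78.0 regions per Mb and ratios of 0.996, 1.01 and 1.01 that did not pass the exact binomial test (adjusted p = 0.90 for each). In the replicate lists the ratio was 1.27 and 1.21 for 2R, 0.830 and 0.840 for 2L, and 0.252 and 0.214 for chromosome 4, where the lists held 12 and 13 regions. How well reads could be placed on chromosome 4 is unknown, so its ratios describe called regions. Among the combined-list regions at or above the median score, X had a ratio of 1.70 (exact binomial test, adjusted p = 5.8e-54) and chromosome 4 one of 0.208. With X left out of that comparison, a setting chosen after the data had been seen, the ratios were 1.28 on 2R, 1.05 on 3R, 0.954 on 3L, 0.807 on 2L and 0.235 on chromosome 4, the order of the full list. Scores in the combined list had a median of 0.494 on X and 0.431 on the long autosomal arms, a difference of 0.0628. Read as log2 ratios, this is 1.04-fold, so a small shift in score went with the ratio of 1.70. The place of X among the arms thus depended on the score threshold.

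**Figure D2:**
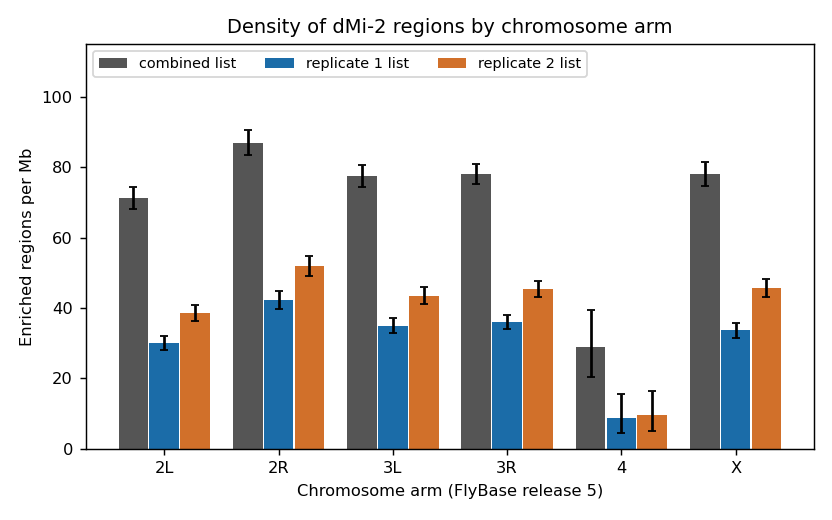
Enriched regions per Mb on each major chromosome arm for the combined list and for each replicate list, with error bars from 95% exact binomial intervals of each arm's share of regions. Arm 2R stands highest in each list (86.9 per Mb in the combined list) and chromosome 4 lowest (28.8 per Mb in the combined list).

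Along the arms, called dMi-2 regions were clustered relative to random placement over whole sequences. In the combined list the median distance to the next region was 3.61 kb, against 7.03 kb for randomly placed regions, and 58.4% of regions had the next one within 5 kb, against 39.0% on average and at most 40.3% for random placements (permutation p = 0.001, one-sided, the smallest that the placements can give). In replicate 1 the share within 5 kb was 31.7% against 17.6%, and in replicate 2 it was 41.1% against 22.6% (permutation p = 0.001 in both). Median distances were 10.21 kb in replicate 1, 7.09 kb in replicate 2 and 8.26 kb among the combined-list regions at or above the median score, against 17.95, 13.56 and 14.71 kb for random placements. On the major arms with regions closer than 1000 bp merged, a setting chosen after the data had been seen, the median distance was 5.55 kb against 9.03 kb. Random placements also fell in stretches where neither replicate held a region, such as 144 of 1208 windows of 100 kb. The comparison thus shows an uneven spread and cannot tell a trait of dMi-2 from where regions could be called. Of 2405 windows of 50 kb, 363 (15.1%) held no combined-list sequence and 168 were covered to at least 50%, with a median coverage of 18.5%.

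**Figure D3:**
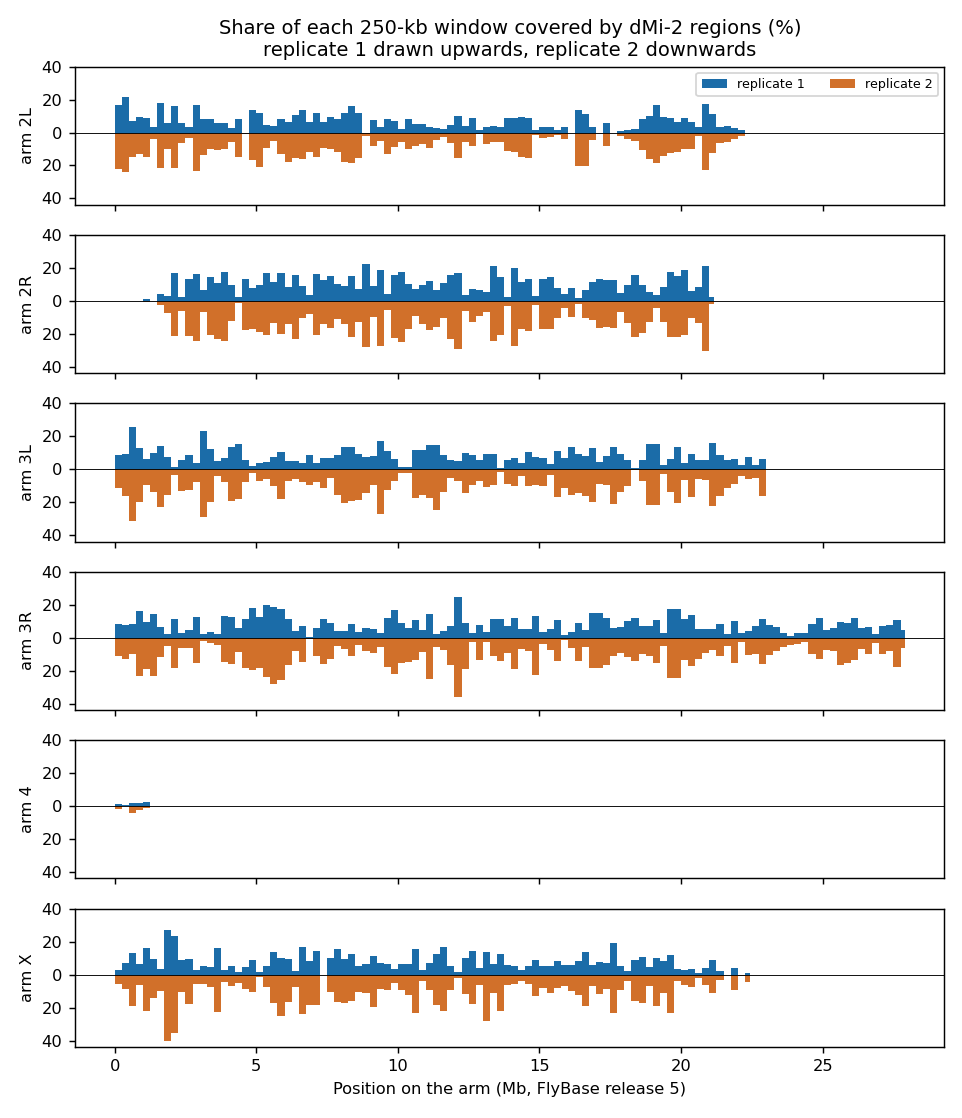
Share of each 250-kb window covered by enriched regions along the 6 major arms, in percent, with replicate 1 drawn upwards and replicate 2 downwards. Window by window the replicates rise and fall together along most of the long arms, and chromosome 4 shows little coverage in either.

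The widest dMi-2 regions spanned 22.1 to 42.9 kb, and both replicates covered each with 2 or more regions. The widest was on 3R at 12029148 to 12072058 (42.9 kb), covered to 72.4% by 6 regions of replicate 1 and to 96.4% by 5 regions of replicate 2. It was followed by X at 2175914 to 2203824 (27.9 kb, 64.3% and 93.8% covered in replicates 1 and 2) and 3L at 623492 to 650662 (27.2 kb, 83.9% and 95.4%). The next were X at 7584440 to 7608054 (23.6 kb, 65.5% and 86.5%) and 2R at 8472630 to 8494758 (22.1 kb, 57.7% and 71.3%). Their scores, from 0.688 to 0.880, were above the median of 0.442 of the combined list, with ranks from 140 to 542 among its 9388 regions. The most densely covered 50-kb windows included 3 of these places. Window 12050001 to 12100000 on 3R was covered to 86.4% and ranked first in both replicates, and window 600001 to 650000 on 3L was covered to 82.1% and ranked second in both. Window 2150001 to 2200000 on X followed with 79.1%, ranked 16 and 3. The others were 9800001 to 9850000 on 3R (76.0%, ranks 35 and 5) and 21000001 to 21050000 on 3L (76.0%, ranks 26 and 20).

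**Figure D4:**
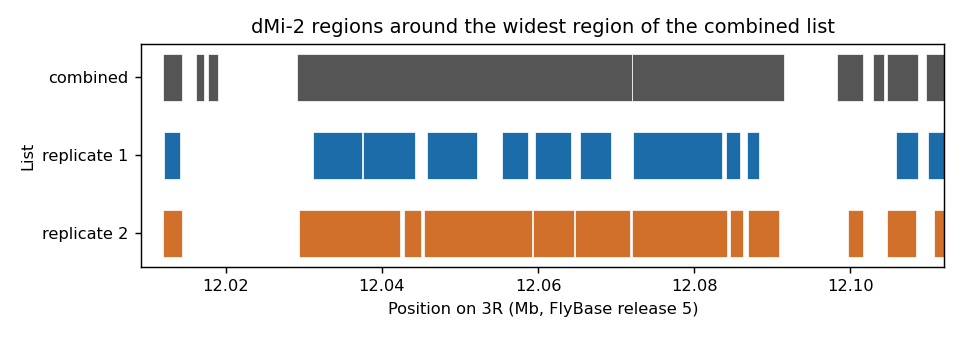
Map of the enriched regions of the 3 lists around the widest combined-list region, on 3R at 12029148 to 12072058 in FlyBase release 5, with each bar an enriched region drawn to scale. The combined region is covered to 72.4% by 6 replicate 1 regions and to 96.4% by 5 replicate 2 regions, and a neighbouring combined region starts at 12072078.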

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

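Both tests of explanations in this part were chosen after the result had been seen. The combined list held 19 regions on the unplaced scaffold U and 28 on the heterochromatic scaffolds, a signal outside the major arms on which the arm comparison rests. Of the 19 on U, 1 overlapped both replicates and 18 neither. Of the 28 on the heterochromatic scaffolds, 5 overlapped 1 replicate and 23 neither. Their densities were 1.89 and 3.02 regions per Mb, against 77.6 on the major arms. Among the heterochromatic scaffolds, the short XHet (0.20 Mb) stood apart with 7 regions, or 34.3 per Mb, of which the replicate lists held 1 each, while 2LHet had 5.42 per Mb, 2RHet, 3LHet and 3RHet had 1.99 to 2.74 and YHet held 0. The unplaced Uextra, which is not among them, held 0 as well.

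The 37 highest scores of the combined list, from 2.08 to 3.57, all belonged to regions that overlapped neither replicate, and 36 of these were narrower than the 1301 bp minimum of the replicate lists. Of the 37, 21 (56.8%, interval 39.5 to 72.9) lay on U or the heterochromatic scaffolds, which held only 47 of all 9388 combined-list regions. These scaffolds were thus strongly overrepresented. The other 16 lay on the major arms, which argues against repetitive scaffolds as the whole explanation. Whether those 16 lie in repeats was not examined. Scores that are ratios of very small whole numbers are a candidate explanation: taken as log2 ratios, all 37 reduce to ratios of whole numbers whose larger term had a median of 8.0 and was at most 16, against a median of 675 in regions that overlapped both replicates. These are ratios in lowest terms, and the read counts behind them are unknown. If so, the highest scores of the combined list may be a poor guide to the strongest dMi-2 regions, and no biological explanation was tested.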

How the results depend on the processing

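The minimum width on the combined list, the permutation of windows, the arm ratios without X, the shifts and width deciles for shared regions, the major arms for the score agreement and the merging for the spacing were chosen after the data had been seen. Of 101 alternative values, 86 kept their direction and side of the threshold, or stayed within the interval of the reported value. The replicate overlap exceeded the circular shifts, the scores of the replicates correlated, and regions were clustered under each alternative tried. Shared regions of replicate 1 had higher scores under each alternative but that within deciles of width, where the difference turned to -0.0196 (-0.0051 with thinly filled deciles kept). In replicate 2 the difference kept its direction there but fell from 0.0868 to 0.00865 (0.0185 with thinly filled deciles kept). Against shifts of the other list both differences stayed above the highest, 0.0318 and 0.0453. The shifts do not hold width equal, as shifted lists gave mean width differences of 106 bp and 226 bp, against 547 bp and 873 bp observed. They thus cannot separate score from width. Within deciles of width the higher score was absent in replicate 1, and only a small part of it remained in replicate 2. The make-up of the combined list moved with the definition of overlap. With a reciprocal overlap of 50%, 20.2% of its regions were in both replicates, 23.8% only in replicate 2 and 47.8% in neither. With centres within 250 bp, 10.1% were in both, 8.81% only in replicate 1 and 61.0% in neither. Without regions narrower than the smallest replicate region, 39.9% were in both, 9.18% only in replicate 1, 23.8% only in replicate 2 and 27.0% in neither, since the regions in neither fell from 3815 to 2020 and all regions from 9388 to 7472. Among combined-list regions at or above the median score, the density ratio passed the threshold on X (1.70), 3L (0.823) and 3R (0.895). On 3R it also turned from above to below 1 (exact binomial test, adjusted p = 0.0023). The moves on 3L and 3R follow from the rise on X, as with X left out of that comparison 3L had 0.954 and 3R had 1.05 (exact binomial test, adjusted p = 0.25 and 0.23). The X ratio over all regions, which did not pass the test, was 0.953 in the replicate 1 list and 1.03 in the replicate 2 list. Its direction thus depended on the list, and the cause was not tested. The permutation of 100-kb windows left the 2L ratio near the threshold (adjusted p = 0.047) and kept 2R (0.0048) and chromosome 4 (6e-04, the smallest that it can give) past it. The tests of genes, promoters and genomic features were not run, because the gene table used here is on another genome release, and the replicate overlap has no value with a replicate left out. No paired analysis was possible because the input libraries have no values of their own in the lists. The labels name each input as the control of 1 ChIP replicate, and the input behind the combined list is not stated in the sources used here. Depth limits how firmly the replicates can be told apart: without read counts it is open whether the additional regions of replicate 2 reflect deeper sequencing.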

Other observations

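Of the tests in this part, those of the score scale, of a constant offset, a higher threshold and a separate scaling factor on X, and of the smaller minimum width were chosen after the result had been seen. The others were set before their results were seen. Called dMi-2 regions were nearly missing from the ends of several arms nearest the centromere. Read counts and read filters are not given, so it is unknown how well reads could be placed there. In the 1 Mb nearest the centromere, 2R and 3L held 0 regions in both replicates, against 44.4 and 36.4 per Mb over the rest of these arms in replicate 1 and 54.4 and 45.3 in replicate 2. Arm 2L held 2 and 4 regions and X held 10 and 19, or 0.064 and 0.0997 times the density of the rest on 2L and 0.288 and 0.405 times on X (exact binomial test, largest adjusted p over these 4 arms and both replicates 1.2e-05). The density was lower on 4 of the 5 long arms, not on all as the hypothesis of sparser regions near every centromere required. On 3R it was 1.27 and 1.34 times that of the rest (exact binomial test, adjusted p = 0.13 and 0.034). The 3R value covers the end of the arm sequence only. The scaffold 3RHet (2.52 Mb) is a separate sequence and held 1.99 regions per Mb in the combined list. These binomial tests take regions as independent although they cluster, and no permutation of windows was run here, so their p-values may be too small. In the combined list the ratios were 0.033 on 2R and 0.0373 on 3L, with 3 regions each, 0.203 on 2L with 15 regions, 0.437 on X with 35 regions, and 1.16 on 3R, which did not pass the exact binomial test (adjusted p = 0.17).

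Dense and sparse stretches of the genome were common to both replicates. Across 1208 windows of 100 kb, the numbers of regions correlated with a Pearson r of 0.856 and a Spearman rho of 0.875, computed across windows, which are not independent replicates. In both lists 144 windows (11.9%) held no region. Regions that were not shared also lay near regions of the other replicate: 55.8% of the 841 unshared replicate 1 regions and 50.2% of the 2112 unshared replicate 2 regions on the major arms were within 5 kb of one, against 29.9% and 25.8% for random placements outside the other list (permutation p = 0.001 in both, one-sided, the smallest that the placements can give). This goes with the hypothesis that the replicates share dense stretches beyond the regions they share.

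The scale of the scores, which the files do not name, can be read from the values. With 1 constant per list subtracted, 99.8% of the combined scores, 4211 of 4213 replicate 1 scores and all 5359 replicate 2 scores equal log2 of a ratio of whole numbers with a denominator of at most 3000, to within 1e-10, against at most 0.112% of random values. The combined list held 193 regions with the same score of 0.403, the constant of that list. At their own constants, replicate 2 held 135 with 0.577 and replicate 1 only 6 with 0.797. The values are consistent with log2 ratios of whole numbers multiplied by 1 scaling factor per list, and differences of scores within a list are then log2 differences.

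Scores on X were higher than on the long autosomal arms in both replicates, with medians of 0.699 against 0.609 in replicate 1 (difference 0.09, 95% interval 0.08 to 0.10 from a bootstrap over 500-kb blocks) and 0.685 against 0.605 in replicate 2 (difference 0.08, interval 0.07 to 0.09). Read as log2 ratios, the differences are small, 1.06-fold in each replicate. Another candidate is a higher threshold on X alone, which removes low-scoring regions and adds none. Among regions at or above the median score, X held 1.68 (interval 1.43 to 1.96) and 1.67 (interval 1.44 to 1.94) times the density of the other major arms (bootstrap intervals). Over all regions the ratios were 0.953 and 1.03, so these higher ratios follow from the higher scores themselves. They argue against such a threshold as the whole cause only if X would otherwise hold the density of the other arms. That density was not measured. A scaling factor of its own for X is argued against too, unless that factor were itself a ratio of whole numbers, since at least 99.9% of the X scores in each list fit the constant of the list. Fewer reads on X, so that a region needs a higher ratio to be called, were examined in strata of width and of the denominator of the ratio. The strata left 101% (interval 88.0 to 112) of the difference in replicate 1 and 93.6% (interval 82.4 to 106) in replicate 2. In the combined list they left 87.6% (interval 77.5 to 96.7, bootstrap intervals). This argues against fewer reads as the whole cause only as far as the denominator tracks depth, which was not checked. It is a rough stand-in for depth, since a ratio in lowest terms loses any common factor of its whole numbers. The denominators were lower on X (medians 213 against 255, 141 against 197 and 232 against 313, in the same order), which goes with fewer reads there and leaves a part open. A constant offset of the ratio on X is a candidate explanation only. The differences at the 5th and 95th percentiles departed by at most 26.3% from that at the median in the replicates. In the combined list they rose from 0.0487 at the 5th percentile to 0.0628 at the median and 0.0806 at the 95th. This check cannot single out an offset, since other causes could raise these percentiles too. An offset under 1 common threshold could also add regions on X, where the ratios over all regions were 0.953 and 1.03. Whether an offset would come from the inputs or from dMi-2 itself was not tested.

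The 3815 combined-list regions that overlap neither replicate had a median width of 1337 bp, against 3799 bp for regions in both. The smaller minimum width of the combined list could account for part of them, as 47.1% (interval 45.5 to 48.6) were narrower than the smallest replicate region, but not for the rest. Calls placed at random along the arms are argued against as the whole cause: of the 3774 on the major arms, 57.7% lay within 5 kb of a replicate region, against 32.9% for random placements outside the replicate regions (permutation p = 0.001, one-sided, the smallest that the placements can give). The share was 54.4% for the narrower and 60.5% for the wider ones. Weak enrichment below the threshold of the replicate lists stays a possible explanation and was not tested, as it would take read counts.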
